A study of Homo sapiens with 12 samples.

How the data were processed

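RNA from 12 samples of A549 cells was labelled with biotin from 1 ug of total RNA per sample and hybridised to a 1-colour Affymetrix expression array with 54675 probe sets, per the labels. Groups were taken from the sample titles: 3 FAM60A knockdown samples with 3 non-targeting controls, and 3 SDS3 knockdown samples with 3 other non-targeting controls, each 3 days after transfection with 50 nM siRNA. The treatment protocol in the labels names only the FAM60A siRNA and the non-targeting siRNA, and siRNA sequences were not used here. No untransfected cells were analysed here.

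The deposited table holds probe set intensity on a linear scale after RMA, which the submitters' processing notes name without a version or settings; whether all 12 arrays were normalized together is not given in the sources used here. The array medians agree within an experiment and differ between experiments, from 186 to 192.6 in the FAM60A experiment and from 96.82 to 98.32 in the SDS3 experiment, so no level was compared across them. RMA forces the arrays it normalizes to a common distribution, so a change shared by most transcripts is removed before any test, and it narrows changes near the background and near saturation. The interquartile ranges (log2) ran from 2.923 to 3.069 on the FAM60A arrays and from 3.277 to 3.344 on the SDS3 arrays. These ranges and the medians argue against normalization of all 12 arrays together. Every per-sample column was used. The values were expected to be on the log2 scale when the design was fixed and proved to be linear, so their log2 was taken; no other step was changed.

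Probe sets were named through the platform annotation: 41097 had 1 gene symbol, 1801 had several and 11777 had none listed. Symbols were updated through Entrez identifiers in RefSeq's gene table of GRCh38.p14, which matched 41043 of the 41097, and no coordinates were used because the array has no genome build of its own. A gene was the probe set with the highest mean over the 12 arrays among those of that gene alone, which gave 19775 genes. Genes with at least 3 of 12 arrays at log2 5 or more were tested, 18621 in all. Of 63 genes named for the FAM60A knockdown, 40 had a further probe set above that level, and another probe set passed in the same direction for 35 of them and in the opposite direction for 0. Of 59 named for the SDS3 knockdown, 40 had a further probe set, 35 of them passing in the same direction and 1, TGFB2, in the opposite direction.

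Each knockdown was compared with its own controls in a fit of 6 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on log2 values, Benjamini-Hochberg adjustment over all tested genes, threshold 0.05). The difference between knockdowns was the contrast of both changes in a fit of all 12 arrays. All adjusted p-values are limma's, and log2 changes are knockdown minus control. The data.table package, version 1.17.8, read the files. Other probe sets of a target gene were taken from a fit of every probe set, with its own adjusted p. Overlaps of calls were tested with Fisher's exact test, one-sided, with the expected number taken from independent lists. The difference in mean signal of control probe sets between knockdown and control was tested with exact permutation over all assignments of 6 arrays, where the smallest two-sided p is 0.1.

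A set of 28 gene lists with 779 genes, 718 of them tested, was fixed before the data were examined and tested with camera, limma's competitive gene set test, with the preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the lists. An estimated correlation and fry, which tests whether a set's genes move one way on balance and does not compare the set with other genes, were alternatives. With an estimated correlation camera also takes its degrees of freedom from the few arrays rather than from the genes. Its p-values then rise even where the genes are not correlated. Named genes followed a rule fixed at the same time: both targets; per knockdown the 8 largest rises and 8 largest falls that passed with non-overlapping arrays; up to 4 members with the largest passing change from the 8 lists with the smallest camera p and from 3 further lists (SIN3-HDAC subunits, TGF-beta components and TGF-beta targets); the 6 largest shared rises and falls; up to 4 genes with opposite calls; and the 5 largest differences in each direction. Any other named gene is said to have been chosen after its values were seen.

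The alternatives were no filter or a filter at log2 7; the mean of all probe sets of a gene; no probe sets of shared sequence where a gene has another; arrays centred on their medians; quantile normalization of the 12 arrays; all 12 arrays in 1 fit; eBayes with trend and robust; array weights; a replicate block; each replicate left out; minimum changes of 1.5-fold and 2-fold; and an adjusted p of 0.01. Probe sets of shared sequence were told by the suffixes _s_at and _x_at of their names, among probe sets annotated to 1 gene. Spike-in scaling was added after seeing the data: each array was scaled to its mean over 12 probe sets for the dap, lys, phe and thr spike-in transcripts. For named genes with a group mean under log2 5, bounds were also added then, as the change with each array's value set to log2 5 where it was lower; that level is the filter's, and detection calls were not used here. Families of genes sharing the first letters of their symbols were also added then.

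The fits were tested on simulated data with the real means and spreads of 18621 genes. In the simulated FAM60A comparison limma recovered 95 of 100 genes changed 1.5-fold and 100 of 100 changed 2-fold; in the SDS3 comparison, 92 and 99 of 100; in the difference, 83 and 99 of 100. With nothing changed, 0 genes were called in each. In the runs with changed genes, 5, 3 and 7 unchanged genes were called in the FAM60A comparison, the SDS3 comparison and the difference. In a simulated FAM60A comparison with 1 list shifted by 0.3, camera called that list and 0 of the others. The simulated noise was drawn independently for each gene, so it does not show how often camera calls lists of correlated genes. Nor does it show how limma's calls behave where noise is shared between genes or where as many genes change as were called here. On the real FAM60A arrays the shifted list, G2/M and mitosis genes, had an estimated correlation of 0.203.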

Results

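Gene expression was measured in A549 cells, a human lung adenocarcinoma line, 3 days after transfection with small interfering RNAs (siRNAs) at 50 nM. One experiment set cells with a FAM60A siRNA against cells with a non-targeting siRNA, and another set cells with an SDS3 siRNA against their own non-targeting controls. Each of the 4 groups held 3 arrays, 12 in all, and no control array served both experiments. FAM60A (current symbol SINHCAF) and SDS3 (current symbol SUDS3) encode subunits of the SIN3-HDAC complex, a co-repressor that brings histone deacetylases to chromatin. The comparisons ask which transcripts change when either subunit is depleted, and where the 2 depletions differ. The median probe set signal lay between 186 and 192.6 on the FAM60A arrays and between 96.82 and 98.32 on the SDS3 arrays, so levels were compared only within an experiment. The labels speak of wells plated in triplicate without naming separate cultures, so p-values measure only the spread between these samples, which may be technical. The small number of arrays limits the precision of every value.

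Each siRNA lowered its own target transcript. SINHCAF went from 11.99 ± 0.0195 (log2 signal, SD, n = 3) in the controls to 9.30 ± 0.163 (n = 3) in the FAM60A knockdown, a log2 change of -2.69 (SE 0.0778, limma adjusted p = 7.76e-09) that left 15.5% of the control level. SUDS3 went from 10.05 ± 0.0463 (n = 3) to 8.47 ± 0.151 (n = 3) in the SDS3 knockdown, a log2 change of -1.58 (SE 0.0777, limma adjusted p = 3.06e-06) that left 33.4%. The other probe set of each gene fell too, to 17.2% for SINHCAF and 37.2% for SUDS3. Both probe sets of SINHCAF and the brighter one of SUDS3 are named as of shared sequence, and the other of SUDS3 is not. SUDS3 had a log2 change of 0.040 in the FAM60A knockdown (adjusted p = 0.698), and its other probe set had -0.28 there (adjusted p = 0.205). Without FAM60A control replicate 2 its change was -0.035. SINHCAF rose by 0.35 in the SDS3 knockdown (adjusted p = 0.00291), a change that its other probe set did not show (log2 change 0.056, adjusted p = 0.772). With spike-in scaling it was 0.028 and did not pass.

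**Figure D1:**
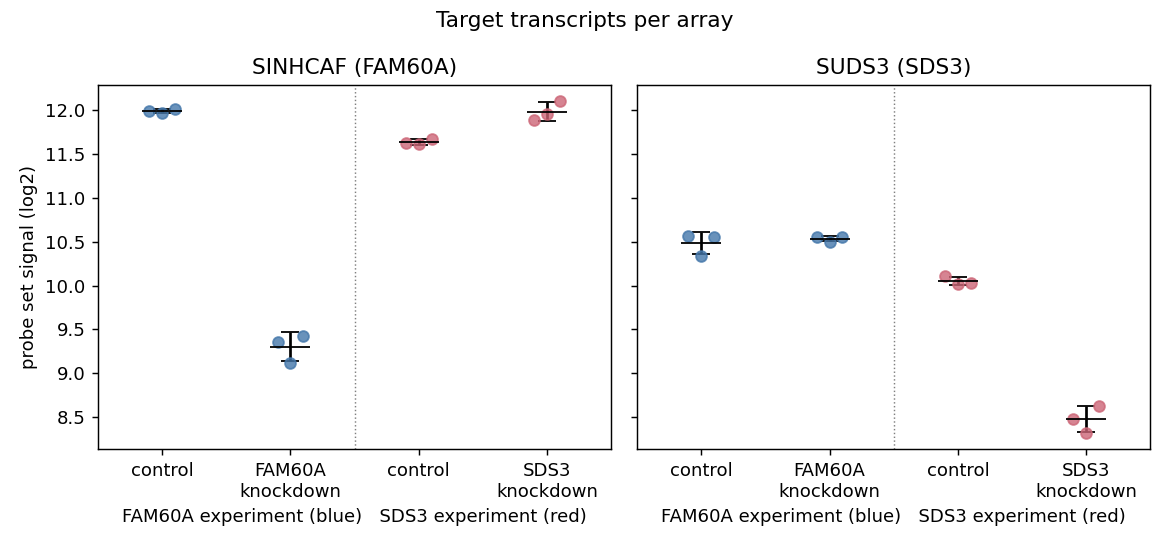
Signal of SINHCAF (left) and SUDS3 (right) on each array, in log2 units on the y axis, with control and knockdown groups of the FAM60A experiment (blue) and the SDS3 experiment (red) on the x axis; points are arrays, horizontal bars are group means and error bars are SDs (n = 3). SINHCAF stands at 9.30 in the FAM60A knockdown against 11.99 in its controls, and SUDS3 at 8.47 in the SDS3 knockdown against 10.05.

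FAM60A knockdown raised NID1, COL5A1 and other genes of the extracellular matrix. NID1, which encodes the basement membrane protein nidogen 1, rose 9.66-fold (log2 change 3.27, SE 0.11, n = 3, adjusted p = 1.38e-08), and COL5A1, a fibrillar collagen chain, rose 7.18-fold (log2 change 2.84, SE 0.0626, adjusted p = 3.51e-09). TAGLN, which encodes the actin-binding protein transgelin, rose by 2.69 on the log2 scale, PXYLP1 by 2.68, the neuronal pentraxin gene NPTX1 by 2.56, LBH by 2.54, the kinase gene HIPK3 by 2.42 and the synaptic vesicle gene SYNGR3 by 2.35. The pentraxin gene PTX3 fell at least 4.64-fold (adjusted p = 1.03e-08), a bound because its knockdown mean, 4.71, lay under the level filter of log2 5. Apart from SINHCAF and PTX3, the largest falls were those of PCYOX1 (log2 change -2.42) and of the granzyme B inhibitor gene SERPINB9 (-2.36). DDC, which encodes aromatic amino acid decarboxylase, followed with -2.34, the ubiquitin-conjugating enzyme variant gene UBE2V2 with -2.33, MTMR2 with -2.30 and the aquaporin gene AQP3 with -2.24. The TAGLN rise came from a probe set of the shared-sequence class: without that class its log2 change was -0.085 and did not pass.

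In total 6855 of 18621 tested genes passed limma at an adjusted p under 0.05 in the FAM60A knockdown, 3577 higher and 3278 lower. At least 2-fold changes were seen in 342 of them, 234 higher and 108 lower. The 3 knockdown arrays lay on one side of all 3 controls for 8953 genes, or 48.1%, where chance gives 10%. Spike-in scaling, chosen after seeing the data, moved the median of all genes by -0.088 and gave 1348 higher and 1967 lower genes. Quantile normalization of the 12 arrays, a planned setting, gave 3384 higher and 3672 lower genes. Which direction held more genes therefore depended on the scaling. The spike-in probe sets stood 0.087 higher (log2) in the knockdown than in the controls (exact permutation p = 0.5, two-sided). The probe sets for 18S ribosomal RNA stood 0.28 higher (exact permutation p = 0.1, two-sided, the smallest that 3 against 3 arrays allow). As a sign of RNA quality, the difference between the 3' and 5' probe sets of ACTB (log2) changed by -0.0945 from control to knockdown (exact permutation p = 0.1, two-sided), and that of GAPDH gave p = 1.

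Of the 28 gene lists, 8 passed camera with its preset correlation in the FAM60A knockdown, and none passed with an estimated correlation, where 5 had an unadjusted p under 0.05. More than the correlation differs between these settings. Targets induced by TGF-beta had an estimated correlation of -0.005, under the preset 0.01, yet their unadjusted camera p went from 6.79e-06 to 0.00693. A list that fails with an estimated correlation is therefore not shown to fail because its genes are correlated. Regrouping the same 6 arrays gave up to 7 lists with the preset correlation. Such groupings keep part of the knockdown's change, so this count is not one of false calls alone. Median, mean and test differed in sign for 5 of the 28 lists, and 0 of these passed. Extracellular matrix genes showed the clearest rise: 23 of 32 measured members rose and none fell (24 and 0 adjusted over the list alone), among them NID1, COL5A1, the collagen I gene COL1A1 (log2 change 2.10) and SPARC (1.68). The list's median change was 0.59 (camera adjusted p = 3.95e-11, adjusted p = 0.0947 with an estimated correlation). Targets induced by TGF-beta rose in 17 of 30 members and fell in 4 (17 and 4 adjusted over the list alone), with COL1A1, the cytokine gene IL11 (1.75) and the basement membrane collagen gene COL4A2 (1.43) among them (camera adjusted p = 6.34e-05, adjusted p = 0.097 with an estimated correlation). Mesenchymal transition genes rose in 9 of 21 members and fell in 1 (9 and 2 adjusted over the list alone), with SPARC, the lysyl oxidase gene LOXL2 (1.30), the gelatinase gene MMP2 (1.08) and the integrin gene ITGA5 (0.65) changing most (camera adjusted p = 0.00667, adjusted p = 0.225 with an estimated correlation). COL1A1 and SPARC each stand in more than 1 of these lists, so the lists are not independent.

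Cell cycle lists were lower in the FAM60A knockdown by camera with its preset correlation. Of 40 genes of G2/M and mitosis, 32 fell and 2 rose (32 and 2 adjusted over the list alone), with the hyaluronan-binding spindle gene HMMR at -0.86, the mitotic kinase gene CDK1 at -0.79, the spindle checkpoint gene MAD2L1 at -0.76 and the kinesin gene KIF4A at -0.73. PRC1, which encodes a protein of the spindle midzone, rose by 0.64. The list had camera adjusted p = 9.08e-09, and adjusted p = 0.306 with an estimated correlation. Of 41 genes of G1/S and DNA replication, 23 fell and 3 rose (28 and 3 adjusted over the list alone), among them GINS1 (-0.76), the replicative helicase gene MCM2 (-0.62), the primase gene PRIM2 (-0.61) and the clamp loader gene RFC3 (-0.53), with camera adjusted p = 0.00015 and adjusted p = 0.243 with an estimated correlation. Genes of MYC and ribosome biogenesis fell in 11 of 22 members and rose in 2 (12 and 2 adjusted over the list alone), led by NOP58 (-0.52), the polyamine synthesis gene ODC1 (-0.52), RRS1 (-0.37) and LYAR (-0.35). This list had camera adjusted p = 0.0207, adjusted p = 0.593 with an estimated correlation. It did not pass with spike-in scaling (adjusted p = 0.0908, the highest over the alternatives with the preset correlation, the lowest being 0.00702).

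Of the metabolic lists, those of hypoxia and of cholesterol synthesis rose in the FAM60A knockdown by camera with its preset correlation. Oxidative phosphorylation genes did not pass, with 2 of 30 higher and 6 lower (2 and 5 adjusted over the list alone; camera adjusted p = 0.357). Hypoxia and glycolysis genes rose in 17 of 30 members and fell in 2 (19 and 4 adjusted over the list alone), with camera adjusted p = 0.000358 and adjusted p = 0.225 with an estimated correlation. The members that moved furthest went both ways: the neuronal enolase gene ENO2 (1.10) and PFKFB4 (0.86) rose, while the glucose transporter gene SLC2A3 (-1.22) and the collagen prolyl hydroxylase gene P4HA1 (-1.09) fell. Cholesterol synthesis genes and SREBP2 targets rose in 10 of 19 members with no fall (10 and 0 adjusted over the list alone), including the methylsterol monooxygenase gene MSMO1 (0.75), the sterol carrier gene STARD4 (0.69), TM7SF2 (0.36) and FDPS (0.33). This list had camera adjusted p = 0.00464, adjusted p = 0.306 with an estimated correlation. It did not pass with spike-in scaling (adjusted p = 0.0526, the highest over the alternatives with the preset correlation, the lowest being 0.00218), and neither did TM7SF2 (log2 change 0.27) and FDPS (0.24).

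Subunits of the SIN3-HDAC complex changed in both directions in the FAM60A knockdown, 5 of 22 higher and 4 lower (5 and 4 adjusted over the list alone; camera adjusted p = 0.97). The scaffold gene SIN3B rose by 0.94 (SE 0.0676, adjusted p = 1.84e-06), SAP30L by 0.88 and PHF12 by 0.44, and with spike-in scaling PHF12 did not pass (log2 change 0.35). Components of TGF-beta and BMP signalling rose in 16 of 44 members and fell in 8 (17 and 10 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.0976). Its largest changes were rises of the ligand gene TGFB2 (log2 change 1.71, SE 0.0605), the latent TGF-beta binding protein gene LTBP3 (1.42) and the receptor gene TGFBR1 (1.41), and a fall of the BMP receptor gene BMPR1B (-1.06). The LTBP3 rise was absent without probe sets of shared sequence (log2 change 0.0063).

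SDS3 knockdown raised NID1 and the actomyosin genes TAGLN and MYL9, and lowered AGR2 and HTR2B. NID1 rose 10.4-fold (log2 change 3.37, SE 0.0735, n = 3, adjusted p = 2.65e-07) and TAGLN 9.11-fold (log2 change 3.19, SE 0.134, adjusted p = 1.66e-06). HIPK3 rose by 2.57 on the log2 scale, the myosin light chain gene MYL9 by 2.33, TMEM170B by 2.32, EMP2 by 2.14, the chloride channel gene CLIC4 by 2.10 and THG1L by 2.05. AGR2, which encodes a disulfide isomerase of secretory epithelium, had a log2 change of -3.25 (SE 0.114, adjusted p = 1.03e-06), and the serotonin receptor gene HTR2B fell at least 4.33-fold, a bound because its knockdown mean, 4.24, lay under log2 5. The cytochrome P450 gene CYP1B1 changed by -2.46, the non-coding RNA LINC00513 by -2.37, the prostaglandin synthase gene PTGS2 by -2.32, the fibrinogen chain genes FGA and FGG by -2.28 and -2.20, and PPEF1 by -2.23.

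In total 6439 of 18621 genes passed limma at an adjusted p under 0.05 in the SDS3 knockdown, 2941 higher and 3498 lower, and 345 changed at least 2-fold, 173 higher and 172 lower. The groups did not overlap for 8867 genes, or 47.6%, where chance gives 10%. The spike-in probe sets stood 0.32 higher (log2) in this knockdown than in its controls, and the 18S ribosomal RNA probe sets 0.53 higher (exact permutation p = 0.1 for each, two-sided, the smallest possible). Scaling each array to the spike-in probe sets, chosen after seeing the data, moved the median of all genes by -0.32 and left 505 genes higher and 9343 lower. Changes in the SDS3 knockdown are given relative to the bulk of the genes. Of the 6 lists that rose by camera, all but the TGF-beta targets (median 0.46) had medians smaller in size than that shift, such as extracellular matrix genes (0.27), NF-kappa B genes (0.23) and hypoxia genes (0.11).

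In the SDS3 knockdown 12 of 28 lists passed camera with its preset correlation, and none passed with an estimated correlation, where 3 had an unadjusted p under 0.05. Regrouping the same 6 arrays gave up to 11 lists with the preset correlation, again with part of the knockdown's change kept. Median, mean and test differed in sign for 6 of the 28 lists, and 0 of these passed. Targets of NRF2, the regulator of the antioxidant response that is active in A549 cells, fell in 20 of 25 members and rose in 1 (21 and 1 adjusted over the list alone), with a median change of -0.42. Among them the glutathione peroxidase gene GPX2 changed by -1.41 (SE 0.106, adjusted p = 2.22e-05), the aldehyde dehydrogenase gene ALDH3A1 by -1.06, the cystine transporter gene SLC7A11 by -1.01 and the epoxide hydrolase gene EPHX1 by -0.91 (camera adjusted p = 7.29e-09, adjusted p = 0.394 with an estimated correlation). Targets induced by TGF-beta rose in 21 of 30 members and fell in 3 (21 and 4 adjusted over the list alone), including TAGLN, ANGPTL4 (1.40), MMP2 (1.35) and COL1A1 (1.11), with camera adjusted p = 5.87e-07 and adjusted p = 0.394 with an estimated correlation. Extracellular matrix genes rose in 17 of 32 members and none fell (18 and 0 adjusted over the list alone), led by NID1, COL5A1 (1.72), SPARC (1.40) and COL1A1 (camera adjusted p = 0.000117, adjusted p = 0.394 with an estimated correlation). Genes of cell motility and invasion rose in 14 of 32 members and fell in 3 (14 and 4 adjusted over the list alone), with rises of the focal adhesion gene ZYX (1.44), MMP2 and the urokinase gene PLAU (1.28) and a fall of the matrilysin gene MMP7 (-1.09). This list had camera adjusted p = 0.000174 and adjusted p = 0.394 with an estimated correlation. Here too some members, such as COL1A1 and MMP2, stand in more than 1 of these lists.

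The 2 cell cycle lists were also lower in the SDS3 knockdown by camera with its preset correlation, though many members did not pass. Of 40 genes of G2/M and mitosis 21 fell and 3 rose (22 and 3 adjusted over the list alone): the spindle assembly gene TPX2 fell to 49.9% of control, the cyclin gene CCNA2 changed by -0.91 and the phosphatase gene CDC25B by -0.84, while the midzone gene PRC1 rose by 0.90 (camera adjusted p = 0.000174, adjusted p = 0.495 with an estimated correlation). Of 41 genes of G1/S and DNA replication 15 fell and 6 rose (17 and 6 adjusted over the list alone), among them the licensing factor gene CDC6 (-0.79), GINS3 (-0.78), the polymerase alpha subunit gene POLA2 (-0.77) and MCM10 (-0.53), with camera adjusted p = 0.00921 and adjusted p = 0.495 with an estimated correlation. POLA2 did not pass without probe sets of shared sequence (log2 change -0.22). Hypoxia and glycolysis genes rose in 12 of 30 members with no fall (12 and 1 adjusted over the list alone), including ANGPTL4, VEGFA (0.93), NDRG1 (0.72) and the histone demethylase gene KDM3A (0.66), with camera adjusted p = 0.000414 and adjusted p = 0.394 with an estimated correlation. NF-kappa B and inflammatory genes rose in 12 of 24 members and fell in 2 (13 and 2 adjusted over the list alone): TNFAIP6 (1.80), IL6 (0.90) and IL32 (0.82) rose, and PTGS2 had the largest change in the list, -2.32 (camera adjusted p = 0.00481, adjusted p = 0.429 with an estimated correlation).

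A further 4 lists passed by less in the SDS3 knockdown. Oxidative phosphorylation genes fell in 10 of 30 members (10 adjusted over the list alone; camera adjusted p = 0.0134, adjusted p = 0.569 with an estimated correlation). The list did not pass with the mean of all probe sets (0.34), without shared-sequence probe sets (0.281) or with spike-in scaling (0.183), and ranged from 0.00357 to 0.34 over the alternatives with the preset correlation, as do the ranges that follow. Interferon and double-stranded RNA response genes fell in 14 of 38 members and rose in 1 (16 and 3 adjusted over the list alone; camera adjusted p = 0.0267, adjusted p = 0.577 with an estimated correlation). They did not pass without knockdown replicate 1 (0.0596) or with a filter at log2 7 (0.109), and ranged from 0.0123 to 0.109. Mesenchymal transition genes rose in 9 of 21 members (9 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.0332, adjusted p = 0.495 with an estimated correlation). They did not pass without knockdown replicate 3 (0.0566), with the mean of all probe sets (0.094), without shared-sequence probe sets (0.128) or with a filter at log2 7 (0.0708), and ranged from 0.000761 to 0.128. Epithelial junction genes fell in 10 of 24 members and rose in 2 (10 and 2 adjusted over the list alone; camera adjusted p = 0.0451, adjusted p = 0.394 with an estimated correlation). They did not pass without control replicate 3 (0.0764), knockdown replicate 1 (0.0594) or knockdown replicate 3 (0.0566), with a filter at log2 7 (0.0758) or with quantile normalization (0.0529), and ranged from 0.0165 to 0.0764.

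SIN3-HDAC subunits went both ways in the SDS3 knockdown: 7 of 22 were higher and 3, SUDS3 among them, lower (8 and 3 adjusted over the list alone; camera adjusted p = 0.793). SIN3B had a log2 change of 0.45, the scaffold gene SIN3A one of 0.42 and FOXK1 one of -0.37. With spike-in scaling SIN3B (log2 change 0.13) and SIN3A (0.094) did not pass, and with the mean of all probe sets FOXK1 did not (-0.11). Components of TGF-beta and BMP signalling rose in 17 of 44 members and fell in 10 (17 and 10 adjusted over the list alone; camera adjusted p = 0.125). The ubiquitin ligase gene SMURF2 rose by 1.21 (SE 0.0474, adjusted p = 1.3e-06) and the TGF-beta activator gene THBS1 by 0.86, and the co-receptor gene TGFBR3 changed by -0.83. TGFB2 had a log2 change of 0.99 from its brightest probe set, 2 of its 4 other probe sets fell, and the mean of all its probe sets gave -0.023 and did not pass.

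**Figure D2:**
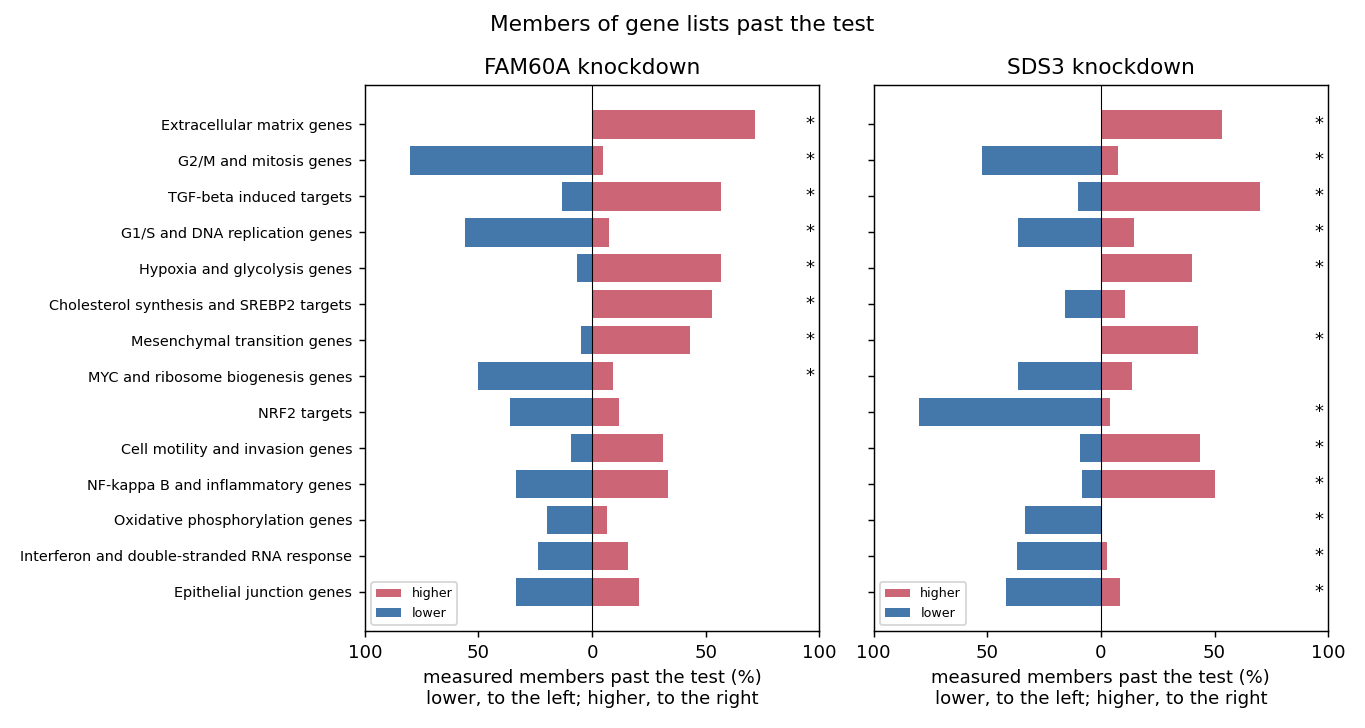
Measured members of each gene list that passed limma in the FAM60A knockdown (left) and the SDS3 knockdown (right), as a percentage on the x axis, with members that fell drawn to the left of 0 in blue and members that rose to the right in red; the lists are those that passed camera in at least 1 knockdown, and an asterisk marks the knockdown in which a list passed. Extracellular matrix genes have 23 of 32 members higher on the left and 17 on the right, and NRF2 targets have 20 of 25 members lower on the right.

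The knockdowns shared many changes. Genes changed in both are ranked here by the smaller of their 2 changes. NID1, TAGLN, HIPK3, EMP2, LSM14A and TMEM170B rose most in both: EMP2 by 2.25 and 2.14 (FAM60A knockdown first), LSM14A, a P-body component gene, by 1.97 and 2.00, and TMEM170B by 1.95 and 2.32. FGA, AGR2, SPX, AQP3, CYP4F3 and LINC00513 fell most in both, with log2 changes of -1.93 and -2.28 for FGA, -1.83 and -3.25 for AGR2, -1.81 and -1.80 for the neuropeptide gene SPX, -2.24 and -1.68 for AQP3, and -1.48 and -2.19 for CYP4F3. TAGLN in the FAM60A knockdown had -0.085 without shared-sequence probe sets. In total 1737 genes rose in both where 565 would be shared by independent lists (one-sided Fisher's exact test, odds ratio 10.8, log10 p = -632), and 1632 fell in both against 615.8 (odds ratio 7.16, log10 p = -455). Fisher's test takes genes as independent, which they are not, so these p-values do not measure the spread between samples. Across 18621 genes, which are not independent replicates, the changes had Pearson's r = 0.557 and Spearman's rho = 0.408. Among genes called in both, 3369 of 3851 (87.5%) went the same way, and among all 18621 genes 60.1% did. Both comparisons used a non-targeting siRNA as the control. With spike-in scaling 379 genes rose in both and 1654 fell.

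**Figure D3:**
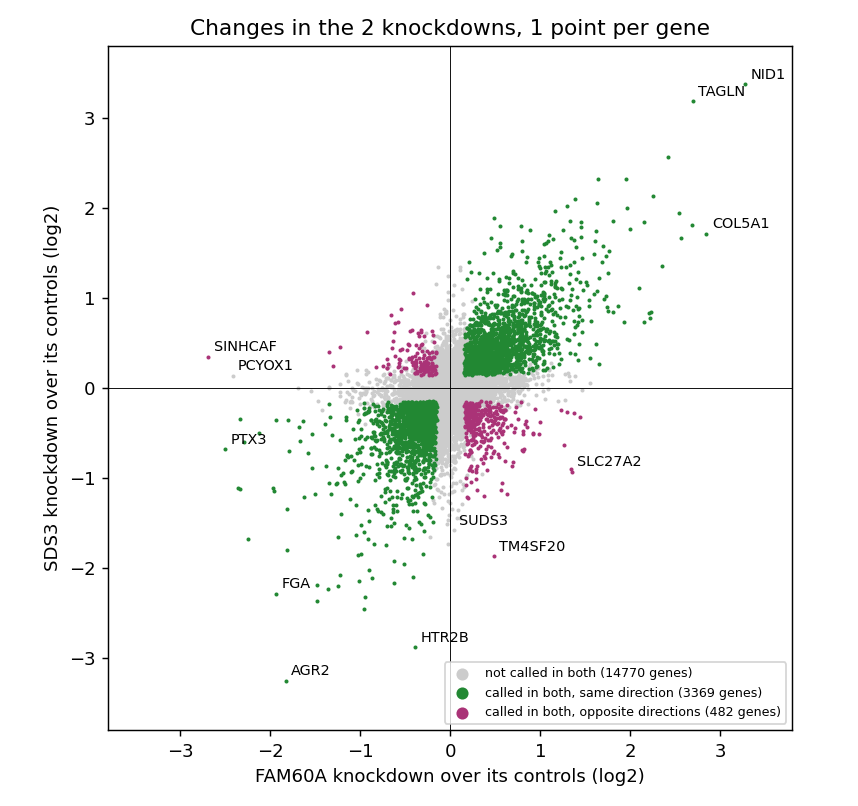
Log2 change of each of the 18621 genes in the FAM60A knockdown (x axis) and the SDS3 knockdown (y axis), both over their own controls; green points passed limma in both in the same direction (3369 genes), purple points in opposite directions (482 genes) and grey points did not pass in both. NID1 lies at 3.27 and 3.37, AGR2 at -1.83 and -3.25, and SLC27A2 at 1.35 and -0.93; HTR2B and PTX3 are drawn at fitted values, each with a knockdown group under log2 5.

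The knockdowns also differed, for shared genes among others: of the 1737 genes that rose in both 520 passed the test of the difference, and of the 1632 that fell in both 476 did. Knockdown and experiment are confounded in this contrast, and the medians and interquartile ranges of the arrays differed between the experiments. The depth of knockdown differed too, with 15.5% of SINHCAF and 33.4% of SUDS3 left. A difference between the subunits cannot be told apart from these. Among the shared genes named above, AGR2 differed by -1.42 (adjusted p = 1.47e-05) and LINC00513 by -0.88. SLC27A2, a fatty acid transporter gene, rose by 1.35 in the FAM60A knockdown and changed by -0.93 in the SDS3 knockdown, and IGFBP1, an insulin-like growth factor binding protein gene, had 1.34 and -0.90. KDELR3 had 0.81 and -0.70. The lipid transporter gene ABCA12 rose by 0.70 in the FAM60A knockdown and was called lower in the SDS3 knockdown, where it lay under log2 5 on all 6 arrays, so no change is given. In all 482 genes were called in opposite directions. Of those, 337 rose in the FAM60A knockdown (671.9 for independent lists) and 145 in the SDS3 knockdown (517.7). The difference itself, SDS3 minus FAM60A, passed limma for 4716 genes, 1861 positive and 2855 negative, and with spike-in scaling for 183 positive and 2475 negative. Besides SINHCAF (3.04) the largest positive differences were those of PCYOX1 (2.56, SE 0.138, adjusted p = 3.77e-08), UBE2V2 (1.99) and RP2 (1.75), and that of PTX3 was at least 1.53. The largest negative ones were those of TM4SF20 (-2.35), SLC27A2 (-2.27), IGFBP1 (-2.24) and the matricellular gene CCN5 (-1.89), and that of HTR2B was -1.72 or further below 0 (adjusted p = 2.33e-07). PTX3 and HTR2B have no rank here, because each was under log2 5 in its own knockdown group.

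Among the lists, 5 differed between the knockdowns by camera with its preset correlation, and none did with an estimated correlation, where 3 had an unadjusted p under 0.05. Median, mean and test differed in sign for 5 lists, and 0 of these passed. NRF2 targets did not pass in the FAM60A knockdown (9 of 25 lower and 3 higher, the same adjusted over the list alone; median -0.081, camera adjusted p = 0.155). They were lower in the SDS3 than in the FAM60A knockdown, with 16 of 25 members past the test of the difference, all negative (17 negative and 1 positive adjusted over the list alone; camera adjusted p = 9.62e-07, adjusted p = 0.384 with an estimated correlation). Extracellular matrix genes had 15 of 32 members with a negative difference and 3 with a positive one (17 and 3 adjusted over the list alone; camera adjusted p = 0.000128, adjusted p = 0.339 with an estimated correlation), and COL5A1 differed by -1.13. Cholesterol synthesis genes and SREBP2 targets had 8 of 19 members with a negative difference (8 adjusted over the list alone; camera adjusted p = 0.00177, adjusted p = 0.339 with an estimated correlation). NF-kappa B and inflammatory genes had 11 of 24 positive and 3 negative (11 and 4 adjusted over the list alone; camera adjusted p = 0.014, adjusted p = 0.519 with an estimated correlation). G2/M and mitosis genes had 15 of 40 positive and 4 negative (15 and 4 adjusted over the list alone; camera adjusted p = 0.014, adjusted p = 0.753 with an estimated correlation), with CDK1 at 0.88 and HMMR at 0.77. Spike-in scaling moved the median difference of all genes by -0.23, which turned the median of the NF-kappa B list from 0.22 to -0.014 (3 positive and 4 negative) and that of the G2/M list from 0.15 to -0.084 (3 and 3), so the direction of these 2 lists is relative to all genes.

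Markers of other cell types did not pass as lists. Of 12 fibroblast markers 3 rose and 1 fell in the FAM60A knockdown (3 and 2 adjusted over the list alone; camera adjusted p = 0.841). In the SDS3 knockdown 5 rose and 1 fell (5 and 1 adjusted over the list alone; camera adjusted p = 0.209). COL1A1, which this list shares with the matrix list, rose in both, LUM fell in both (log2 changes -0.60 and -0.85), and DCN did not pass in either (-0.18 and 0.095). COL3A1 rose in the FAM60A knockdown (0.26, adjusted p = 0.0388) and had -0.15 in the SDS3 knockdown, while COL1A2 had -0.073 in the FAM60A knockdown and rose in the SDS3 knockdown (0.39, adjusted p = 0.00102). PDGFRA did not pass in either (-0.14 and 0.056). These members were named after their values were seen. The 12 endothelial markers had camera adjusted p = 0.57 and 0.861 in the FAM60A and SDS3 knockdowns, and the 15 leukocyte markers 0.546 and 0.676.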

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

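Of the tests below, those of the non-targeting siRNA, of the other probe sets and of falls in 1 knockdown only, spike-in scaling as a setting, the rule on when its test can decide, and the level set for dim values, were chosen after the result was seen. The difference between the knockdowns passed limma for 4716 genes. The difference was negative for SLC27A2 (-2.27), IGFBP1 (-2.24), KDELR3 (-1.51) and ABCA12 (-1.52), which had opposite calls in the 2 knockdowns. ABCA12 lay under log2 5 on all 6 SDS3 arrays, and with values under that level set to it the difference was -0.70. The lists that differed were NRF2 targets (camera adjusted p = 9.62e-07), extracellular matrix genes (0.000128), cholesterol synthesis genes (0.00177), NF-kappa B and inflammatory genes (0.014) and G2/M genes (0.014). With an estimated correlation none of them passed (adjusted p = 0.384, 0.339, 0.339, 0.519 and 0.753 in that order). With spike-in scaling the medians of the NF-kappa B and G2/M lists turned from 0.22 and 0.15 to -0.014 and -0.084. Among probe sets outside the gene tests, the spike-in probe sets stood 0.321 higher in the SDS3 knockdown than in its controls. The 18S ribosomal RNA probe sets stood 0.277 higher in the FAM60A knockdown and 0.53 higher in the SDS3 knockdown. Of 9229 probe sets with no listed gene, 1327 passed limma in the FAM60A knockdown and 1134 in the SDS3 knockdown.

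More genes rose than fell at least 2-fold in both knockdowns, 94 against 31. With spike-in scaling 45 rose and 61 fell, so rises made up 42.5% in place of 75.2%, but such scaling shifts all genes alike and would lower the share whatever the cause, and the spike-in difference in the FAM60A experiment (0.087, exact permutation p = 0.5) lay within its spread, so normalization and a real excess of rises cannot be told apart. The non-targeting siRNA, used in the controls of both experiments, is a further candidate source, since its own silencing would appear as a rise in both. Of the 94 genes 36 differed between the knockdowns, with the rarer direction at 47.2%. A control effect that entered both experiments by 1 common ratio would put nearly all on one side, but that common ratio is an assumption. Spike-in scaling gave 1 and 17, and the remaining 58 were not told apart. Silencing by the control siRNA and an effect of losing either subunit cannot be told apart here, because every change was read against that siRNA and no untransfected cells were analysed.

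Among genes changed at least 2-fold in 1 knockdown and by less than 0.2 (log2) in the other, falls made up 29 of 48 in the FAM60A and 38 of 48 in the SDS3 knockdown, 67 of 96 together, against 31 of 125 for genes changed 2-fold in both (Fisher's exact test, two-sided, odds ratio 6.93, p = 2.48e-11). Fisher's test here and below takes genes as independent and was run on counts already seen, so its p-values add no support to the pattern. The direction in the FAM60A knockdown depended on the scaling: with spike-in scaling falls made up 10 of 39 there and 112 of 114 in the SDS3 knockdown, 122 of 153 together against 61 of 106 (Fisher's exact test, two-sided, odds ratio 2.89, p = 0.000163). All 29 and all 38 falls without that scaling passed the test of the difference, though they were picked for differing. Faulty single probe sets could contribute: of 87 other probe sets of these falling genes 58.6% fell and 3 rose, and a faulty probe set cannot be told apart from other probe sets that miss the transcript. Silencing of further transcripts by each siRNA, and roles of each subunit outside the shared complex, both stay open and were not tested, since no other siRNA against either gene was analysed here.

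NRF2 targets were lower after SDS3 than after FAM60A knockdown, with a median difference of -0.30 over 25 members, and did not pass in the FAM60A knockdown (9 lower, 3 higher, camera adjusted p = 0.155). The values argue against compression of bright signals on the FAM60A arrays: among 649 other genes at log2 13 or more, the SD of changes there was 0.848 of that in the SDS3 knockdown, and the 7 dimmer NRF2 targets had a median difference of -0.38. They also argue against a shift shared by genes of the same signal level, since 0% of 10000 random lists matched on level had a median as low, the lowest being -0.20. A lower NRF2 output after loss of SDS3 may be the cause, as a hypothesis found and tested on the same data. An effect of the SDS3 siRNA on another transcript was not tested and stays open, and the list did not pass with an estimated correlation (adjusted p = 0.384). Subunit, experiment and depth of knockdown cannot be told apart for this difference.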

How the results depend on the processing

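Spike-in scaling was chosen after seeing the data; the other settings were planned. Spike-in scaling gave 3315 FAM60A genes, 9848 SDS3 genes, 2033 shared genes and 2658 differences; its shift of all genes by the spike-in level is part of its construction. Minimum changes of 1.5-fold left 1367, 1296 and 527 shared genes, 2-fold left 342 and 345, and an adjusted p of 0.01 left 4277 SDS3 genes and 2187 shared. Camera with an estimated correlation called 0 lists in each knockdown (5 and 3 at an unadjusted p under 0.05), with its degrees of freedom also taken from the arrays. The alternative fry called 17 in the FAM60A knockdown, testing another question. Leaving out single replicates gave 5806 to 6406 FAM60A genes, 5193 to 6201 SDS3 genes, 2915 to 3222 shared genes, 3945 to 4890 differences, r of 0.532 to 0.566, SINHCAF changes of -2.75 to -2.60, SUDS3 changes of -1.66 to -1.50, 8 to 9 and 10 to 12 lists, and 131 of 131 named calls. SUDS3, not called in the FAM60A knockdown, turned to -0.12 with the mean of probe sets, -0.28 without shared-sequence probe sets, -0.048 with spike-in scaling and -0.035 without FAM60A control replicate 2 (-0.035 to 0.083 over single replicates left out); TGFB2 in the SDS3 knockdown turned to -0.023 with the mean of probe sets, and TAGLN in the FAM60A knockdown to -0.085 without shared-sequence probe sets; the cause was not tested. Same-numbered arrays did not deviate together (correlations from -0.12 to 0.034), so replicate numbers do not pair them; with a replicate block there were 6239 FAM60A genes, 5848 SDS3 genes, 2995 shared genes and 4003 differences, and 8 and 12 lists. Of 2291 further values of named genes 2276 kept direction and side of the threshold. Signal over background limits dim genes, of which 1154 were not tested.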

Other observations

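The tests of gene families, the choice of the genes below and the range of splits of both experiments came after the results were seen. The fibrinogen chain genes FGA, FGB and FGG had log2 changes of -1.93, -0.99 and -1.25 in the FAM60A knockdown and -2.28, -1.84 and -2.20 in the SDS3 knockdown. FGL1, a fibrinogen-like protein gene, had -0.87 and -2.11, and the apolipoprotein gene APOH -0.63 and -1.92, with negative differences for FGB, FGG, FGL1 and APOH (limma adjusted p = 0.000503, 0.000166, 4.43e-06 and 2.13e-05) and none past the threshold for FGA (adjusted p = 0.136). FGB, FGL1 and APOH were chosen after their values were seen. Among the epithelial junction genes, also chosen after their values were seen, the E-cadherin gene CDH1 changed by -0.49 in the FAM60A knockdown and by -1.52 in the SDS3 knockdown, and EPCAM by -1.22 and -0.58, with differences of -1.04 and 0.65. The epithelial junction list did not pass in the FAM60A knockdown, where 8 of 24 members fell and 5 rose (9 and 5 adjusted over the list alone; camera adjusted p = 0.357).

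Families of genes that share the first letters of their symbols, 226 with at least 10 tested genes, were tested with camera after seeing the data. The mitochondrial ribosomal protein genes of the large subunit fell in 31 of 49 members in the FAM60A knockdown, where 1 rose, and in 28 in the SDS3 knockdown (camera adjusted p = 2.4e-05 and 1.23e-05, adjusted p = 0.989 and 0.972 with an estimated correlation). Collagen genes rose in 19 and 17 of 41 and fell in 1 each (camera adjusted p = 0.000278 and 0.00528, adjusted p = 0.989 and 0.972 with an estimated correlation). The collagen median in the SDS3 knockdown, 0.14, was smaller in size than the shift of spike-in scaling there, so its direction is relative to all genes. Ciliary transport genes of the IFT family fell in 10 of 18 members in the SDS3 knockdown (camera adjusted p = 0.00528, adjusted p = 0.972 with an estimated correlation) and differed between the knockdowns (camera adjusted p = 0.00206, adjusted p = 0.989 with an estimated correlation). With an estimated correlation camera called 0 of the 226 families in the FAM60A knockdown, the SDS3 knockdown and the difference (5, 7 and 7 at an unadjusted p under 0.05), against 7, 9 and 3 with the preset one.

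Regrouping the 6 arrays of an experiment gives 10 splits, too few for a share under 0.05. The real split, the 1 with the highest count in each case, gave 6855 genes in the FAM60A and 6439 in the SDS3 experiment, and the highest of the others gave 0 by limma (489 and 547 at an unadjusted p under 0.05, against 8335 and 8133). Every other split mixes knockdown and control arrays, so the knockdown's changes add to the spread within its groups. Their low counts therefore do not measure what arrays without any change would give. For camera with its preset correlation the real splits gave 8 and 12 lists and the highest other splits 7 and 11. At an unadjusted p under 0.05 the real splits gave 11 and 12 lists and the highest other splits 12 and 12, so by count the real groups did not stand out. Every other split has more knockdown arrays on one side than on the other, so part of the knockdown's change stays in it. The list counts of other splits therefore do not measure how often camera calls lists without any change. For the difference and the shared genes, 100 splits of both experiments were counted, the real one and others drawn at random. The split that swaps knockdown and control in 1 experiment alone was not among those drawn. The real one, 1 of 100, gave the highest counts (4716 and 3369), and the highest of the others were 2569 and 0. Of the others 19 kept the real groups of 1 experiment and gave 847 to 2569 differences, while the 80 that mixed the groups of both gave 0, since each knockdown's own changes then add to the spread within groups. Because both counts rest on groups that have 10 splits per experiment, no share under 0.05 can be had for either experiment.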
